A study of Rattus norvegicus with 5 samples.

How the data were processed

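Total RNA ratios were read from 5 two-colour Agilent whole-genome rat arrays, each with 1 kaolin cortex sample in Cy3 and 1 saline cortex sample in Cy5, per the labels. The labels do not say whether each sample was a single animal; the series design gives 5 treatment samples and 5 saline controls. The p-values of single probes therefore measure the spread between arrays. The scanner files were made with Agilent Feature Extraction 10.1.1.1, per the file headers. Per the file headers, the mean spot signal and the local background of each channel are raw intensity values, and the processed signals are intensity values after the software's background subtraction and its linear and lowess dye normalization. Per the file headers, the software's log ratio is the log10 of Cy5 over Cy3. Spot flags for background, saturation and outliers are other values, 0 or 1, per the file headers. The deposited series matrix holds log2 ratios of Cy3 over Cy5; how the authors normalized them is not given in the sources used here. Their direction was settled from the values, since each column ran opposite to its array's log10 ratio (correlation across probes from -1.00 to -0.978). Their column medians were 0.02, -0.05, -0.02, 0.09 and -0.10.

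The following choices were fixed before the data were examined. Spots marked as non-uniform or population outliers (between 86 and 147 per array) were left out. Mean signals minus local background were corrected with normexp (offset 50) and normalized within each array by loess, with control spots given no weight, and spots of one probe were averaged. The value analysed was the log2 ratio of kaolin over saline. A probe was tested when it was well above background in at least 1 channel on at least 3 of the 5 arrays, which kept 29114 of 41012 probes. No spot was saturated. Local background had medians of 21 to 22 in the kaolin channel and 54 to 60 in the saline channel.

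Ratios were fitted with lmFit and eBayes in limma 3.58.1 under R 4.3.3 (files read with data.table, version 1.17.8), as an intercept against 0, two-sided, with Benjamini-Hochberg adjustment over tested probes and a threshold of 0.05. The array was the pairing unit. No dye term could be fitted, since the dyes were never exchanged.

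Probes were given current gene symbols from the reference annotation. Names came for 10768 by accession, 89 by another accession listed for the probe, 5049 by symbol and 3390 by an older symbol, while 21716 kept the name in the file. This gave 19248 probes with an official symbol and 15062 different symbols. A few list members were matched by hand after the files were seen (transferrin and alpha-globin under their current symbols, and Xist through a transcript tag). Probe positions are those of the array files on rn4; no gene models on that build were used, so exon and UTR positions are not given. A gene is its brightest probe. Of 2913 genes with more than 1 tested probe, 966 had another probe with the opposite sign.

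A total of 37 gene lists (594 genes, 16 of them in more than 1 list) were fixed from textbook knowledge of cortical cell types, neighbouring tissue and brain injury, 35 of them for the adjustment and 2 as checks. They were tested with camera in limma, which asks whether a list's genes lie apart from the other genes, with its preset correlation between genes, two-sided and adjusted over the 35 lists. Camera with a correlation estimated per list and fry were run beside it. The estimate was 0.83 for the reactive astrocyte list and 0.89 for the complement list. P-values with the preset correlation compare a list's genes with other genes and do not measure the spread between arrays. Members were also adjusted over the list alone. A list's value is the median over its members on each array, given as the mean and SD over 5 arrays.

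The rule for named genes took the largest changes past the threshold in each direction and members of shifted lists past the threshold. With fewer than 10 genes past it, as here, it took the 8 genes with the smallest unadjusted p in each direction. These came from tested genes with an official symbol, with no further filter on sign or background. A panel of 20 genes was fixed to be named whatever their values. Some genes that these rules take are not reported here. A further 73 genes were chosen after their values were seen: the 3 members of each shifted list with the smallest p in the list's direction, the 4 genes with the largest values in each direction that passed without replicate 2, and markers of the pineal gland. Rsad2, Uty, members that passed over their list alone and other probes of named genes were also singled out after their values were seen.

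Alternatives changed one choice at a time, except that the processed signals, the authors' series matrix and the software's log ratios replace background correction and normalization together. They were no background subtraction, normexp with offset 0, the processed signals with median centring, median centring in place of loess, quantile scaling of average intensity between arrays, the authors' series matrix, the software's log ratios, no filter on dim probes, a stricter filter, saturated spots left out, 10 unpaired channels as 2 groups, eBayes with trend and robust settings, array weights, slide as a random block, each replicate left out in turn, and the mean of a gene's probes for the lists. A further 3 were chosen after seeing the data: the sign of replicate 2 turned, neighbouring-tissue genes left out, and the estimated correlation with each replicate left out.

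The fit was tested on simulated data with 29114 probes, some of them changed by set amounts. Noise was drawn for each probe on its own, so simulated genes did not vary together as those of the real lists did. The counts of called probes and lists therefore hold for uncorrelated genes only. At the real spread and with a straight dye curve, 18 of 67 probes changed by a log2 of 0.5 were called, 52 of 67 changed by 1 and 64 of 66 changed by 2, and 6 of 141 calls were of unchanged probes. The shifted list was called and 0 of 34 unshifted lists were; with an estimated correlation the shifted list was not called at the real spread and was called at a spread 0.5 times it. With a dye curve bent at the bright end, 215 of 405 calls were of unchanged probes, 174 of them above a log2 intensity of 15, at a spread 0.5 times the real one. In that case 1 of 34 unshifted lists was called. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.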

Results

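Parietal cortex RNA of rats injected with kaolin was compared with that of saline-injected rats on 5 two-colour oligonucleotide arrays. Kaolin is a clay that blocks the flow of cerebrospinal fluid and so enlarges the ventricles (hydrocephalus). The injection was given on postnatal day 1 and the tissue came from postnatal day 22, which is post-kaolin day 21. Each array carried 1 kaolin sample in Cy3 and 1 saline sample in Cy5, so there were 5 samples per group and 5 direct comparisons. No array had the dyes exchanged, so the dye and the treatment cannot be told apart. Replicates 1 to 4 shared a slide and replicate 5 was on another. Of 41012 probes, between 27956 and 29385 were well above background in the kaolin channel of an array and between 27372 and 28930 in the saline channel. The median spot signal, before background was subtracted, ran from 95.8 to 117.03 in the kaolin channel and from 152 to 189 in the saline channel. The number of arrays limits the precision of every value.

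To find which genes and cell types differ in cortex 21 days after kaolin, the log2 ratio of kaolin over saline was examined per probe and per gene list. Lists of reactive astrocyte, complement, microglial, antigen-presentation and interferon-response genes lay above the other genes in kaolin cortex. Lists of cholesterol-synthesis, choroid plexus, synaptic and interneuron genes lay below them. Gfap, the intermediate filament of astrocytes, had a mean log2 ratio of 1.81 ± 1.23 (SD, n = 5), a 3.51-fold value, and was positive on 5 of 5 arrays. Ttr, the thyroid hormone carrier made by the choroid plexus, had a mean of -2.85 ± 1.80 (SD, n = 5). In limma, 0 of 29114 probes passed an adjusted p of 0.05 (smallest adjusted p = 0.243), while 20 of 35 lists passed the list test that presets the correlation between genes, 11 upward and 9 downward. With the correlation estimated per list, 0 of 35 lists passed and 0 had an unadjusted p under 0.05.

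The 5 largest list values came from glial and immune genes. The reactive astrocyte list had a median log2 ratio of 1.32 ± 1.29 (SD, n = 5) over its 14 measured members, 13 of them with positive means (adjusted p = 7.81e-06; adjusted p = 0.479 with an estimated correlation). Its members included Vim, another intermediate filament, at 1.58 ± 1.42 and S100a10, a calcium-binding protein family member, at 0.87 ± 0.72. The complement list stood at 1.11 ± 1.01 with 15 of 15 members positive (adjusted p = 5.05e-07; adjusted p = 0.479 with an estimated correlation), among them C3 at 1.90 ± 1.37, C2 at 1.65 ± 1.19 and C1qb at 1.51 ± 1.06. The microglia and macrophage list stood at 0.76 ± 0.76 with 14 of 14 positive (adjusted p = 2.38e-05; adjusted p = 0.479 with an estimated correlation). Tyrobp, a signalling adaptor of microglia, was at 1.53 ± 1.11, Cd68 at 1.27 ± 1.26 and Aif1 at 1.12 ± 0.84. Antigen-presentation genes stood at 0.68 ± 0.59 with 14 of 14 positive (adjusted p = 4.27e-06; adjusted p = 0.479 with an estimated correlation); the class I genes RT1-A2 and RT1-CE10 were at 1.30 ± 1.06 and 0.93 ± 0.46. Interferon-response genes stood at 0.64 ± 0.62 with 18 of 19 positive (adjusted p = 4.79e-06; adjusted p = 0.479 with an estimated correlation), led by Ifitm3 at 1.54 ± 1.31. Rsad2 was the exception at -0.37. The cytokine and chemokine list stood at 0.29 ± 0.30 with 13 of 17 positive (adjusted p = 0.0202; adjusted p = 0.599 with an estimated correlation), with Ccl2, a monocyte attractant, at 1.83 ± 1.61. The cytokine call was lost without replicate 3 (adjusted p = 0.0728), without replicate 4 (adjusted p = 0.0592) and with a stricter filter on dim probes (adjusted p = 0.221); over the settings that keep the preset correlation it ranged from 0.00063 to 0.221, and fry gave 0.297. Adjusted over the list alone, 15 complement, 11 reactive astrocyte, 13 interferon (12 higher, with Rsad2 lower), 10 antigen-presentation, 7 microglial and 0 cytokine members passed, against 0 in each list over all genes. Each of these counts was 0 without replicate 3, without replicate 4 or without replicate 5; without replicate 1 they were 14, 13, 18, 10, 11 and 6, and without replicate 2 they were 15, 13, 17, 11, 10 and 10. Higher in kaolin were 17 of the 18 interferon genes without replicate 1, and 16 of the 17 interferon and 8 of the 10 cytokine genes without replicate 2.

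**Figure D1:**
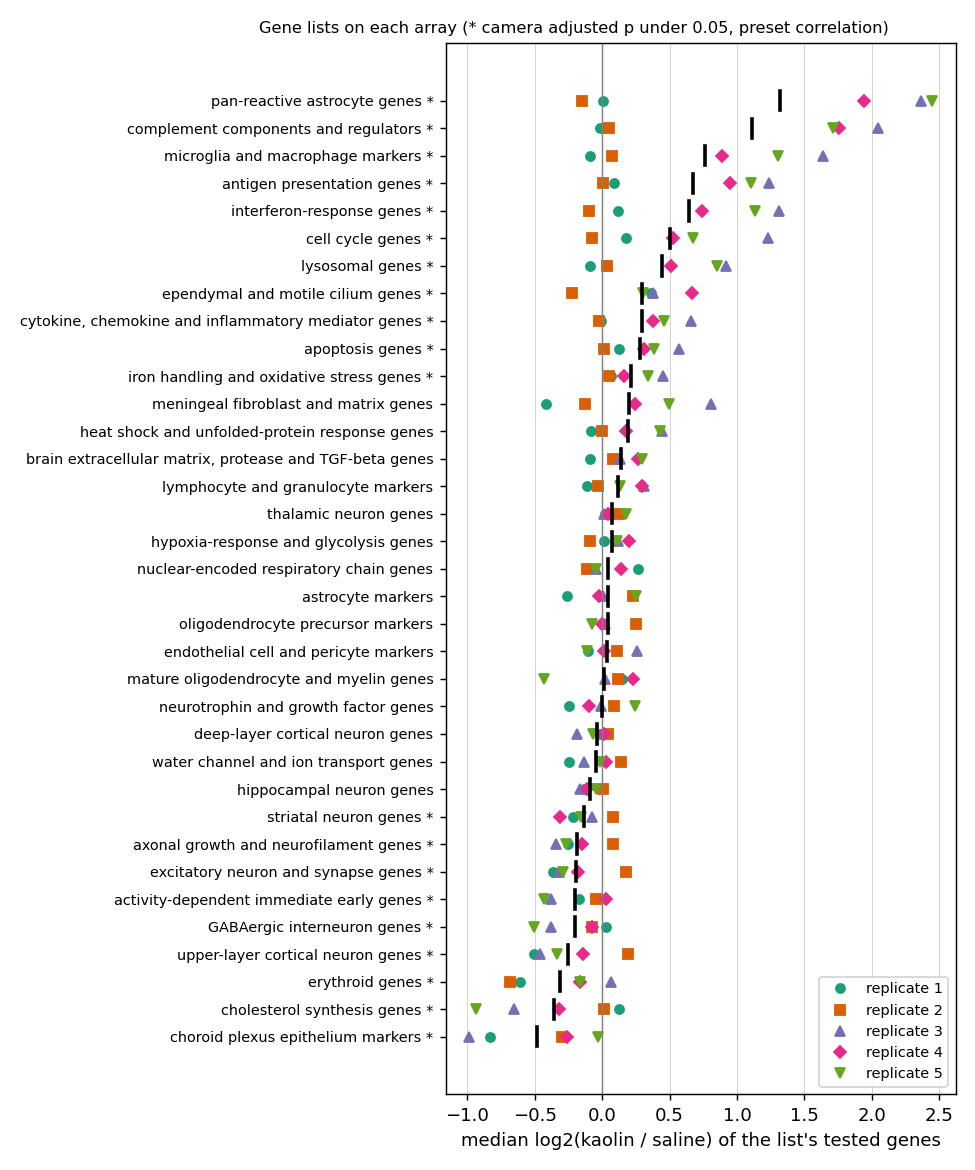
Median log2 ratio of kaolin over saline of each fixed gene list (horizontal axis, log2) on each of the 5 arrays (points, coloured by replicate), with the mean over arrays as a black bar. The reactive astrocyte and complement medians lie between 1.71 and 2.45 on replicates 3, 4 and 5 and between -0.15 and 0.05 on replicates 1 and 2.

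The list medians were not alike on the 5 arrays. Complement medians were -0.01 and 0.05 on replicates 1 and 2, and 2.05, 1.76 and 1.71 on replicates 3, 4 and 5. Reactive astrocyte medians were 0.01, -0.15, 2.36, 1.94 and 2.45 in the same order, and microglial medians -0.09, 0.08, 1.64, 0.89 and 1.30. Gfap was at 0.39 and 0.60 on replicates 1 and 2 and at 2.81, 2.32 and 2.95 on the others.

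Genes of cell division, cell death, lysosomes and iron handling were shifted upward as lists, with lower medians on replicates 1 and 2 than on the others. In the order of replicates 1 to 5 the medians were 0.18, -0.08, 1.23, 0.52 and 0.67 for cell cycle genes and -0.09, 0.03, 0.92, 0.51 and 0.85 for lysosomal genes. They were 0.12, 0.01, 0.57, 0.31 and 0.39 for apoptosis genes and 0.06, 0.05, 0.45, 0.16 and 0.34 for iron-handling genes. Those of ependymal genes were 0.36, -0.22, 0.38, 0.66 and 0.30. Cell cycle genes stood at 0.51 ± 0.50 (SD, n = 5) with 17 of 17 positive (adjusted p = 4.25e-06; adjusted p = 0.479 with an estimated correlation), among them the mitotic kinase genes Cdk1 at 1.14 ± 1.00 and Aurkb at 0.48 ± 0.29. Lysosomal genes stood at 0.44 ± 0.46 with 18 of 18 positive (adjusted p = 6.34e-06; adjusted p = 0.479 with an estimated correlation), with the glucuronidase gene Gusb at 0.60 ± 0.48 and the protease gene Ctsl at 0.35 ± 0.26, which median centring took to 0.02. Apoptosis genes stood at 0.28 ± 0.22 with 15 of 18 positive (adjusted p = 0.00131; adjusted p = 0.479 with an estimated correlation); Casp1 was at 0.78 ± 0.63, Casp6 at 0.49 ± 0.25 and Bax at 0.32 ± 0.13, which median centring took to 0.07. Iron-handling and oxidative-stress genes stood at 0.21 ± 0.18 with 16 of 18 positive (adjusted p = 0.00131; adjusted p = 0.479 with an estimated correlation), with the heme-degrading Hmox1 at 1.40 ± 1.27 and Gpx1 at 0.84 ± 0.80. Ependymal and motile cilium genes stood at 0.30 ± 0.32 with 9 of 10 positive (adjusted p = 0.0115; adjusted p = 0.540 with an estimated correlation), with Foxj1, a regulator of motile cilia, at 0.94 ± 0.89 and the dynein gene Dnai2 at 0.67 ± 0.46. Adjusted over the list alone, 8 cell cycle, 7 apoptosis, 0 lysosomal, 0 iron-handling and 0 ependymal members passed, against 0 in each over all genes. Without replicate 1 these counts were 0, 8, 15, 3 and 0, without replicate 2 they were 14, 13 (11 of them higher), 12, 5 and 6, and without replicate 3, 4 or 5 each was 0.

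Neuronal and lipid-synthesis lists were shifted downward, by less than the 5 largest upward shifts. Cholesterol-synthesis genes stood at -0.35 ± 0.45 (SD, n = 5) with 19 of 20 negative (adjusted p = 5.05e-07; adjusted p = 0.479 with an estimated correlation), with medians of 0.12 and 0.02 on replicates 1 and 2 and of -0.65, -0.32 and -0.93 on the others. Its members included Msmo1 at -0.77 ± 0.61, Sc5d at -0.55 ± 0.50 and the regulator Srebf2 at -0.27 ± 0.23. Immediate early genes, which are induced by neuronal activity, stood at -0.20 ± 0.20 with 13 of 15 negative (adjusted p = 0.00415; adjusted p = 0.479 with an estimated correlation), among them Arc at -1.04 ± 1.13, Nr4a1 at -0.96 ± 0.87 and Egr1 at -0.65 ± 0.68. Excitatory synapse genes stood at -0.20 ± 0.22 with 15 of 20 negative (adjusted p = 0.00118; adjusted p = 0.479 with an estimated correlation), with the glutamate receptor subunit Gria2 at -0.44 ± 0.31 and Nrgn at -0.37 ± 0.25. Interneuron genes stood at -0.20 ± 0.23 with 13 of 15 negative (adjusted p = 0.00129; adjusted p = 0.479 with an estimated correlation), with the neuropeptides Npy at -0.32 ± 0.16 and Sst at -0.28 ± 0.29. Axonal growth genes stood at -0.18 ± 0.16 with 11 of 15 negative (adjusted p = 0.00227; adjusted p = 0.479 with an estimated correlation), with the microtubule-associated Map1b at -0.75 ± 0.65. Striatal neuron genes stood at -0.14 ± 0.15 with 10 of 12 negative (adjusted p = 0.00415; adjusted p = 0.479 with an estimated correlation), with Penk at -0.49 ± 0.33. Upper-layer cortical neuron genes stood at -0.25 ± 0.28 with 8 of 9 negative (adjusted p = 0.0233; adjusted p = 0.479 with an estimated correlation), with the transcription factor Lhx2 at -0.41 ± 0.33. On replicate 2 the excitatory synapse (0.18), upper-layer (0.19), axonal (0.08) and striatal (0.08) medians were positive, as were the interneuron median on replicate 1 (0.03) and the immediate early median on replicate 4 (0.03). The upper-layer call was lost without replicate 1 (adjusted p = 0.143), without replicate 5 (adjusted p = 0.0641) and with median centring (adjusted p = 0.0754), over a range from 0.0013 to 0.143 in the settings that keep the preset correlation and 0.329 in fry. Adjusted over the list alone, Tubb2b passed in the axonal list and 0 members in the other 6 lists, against 0 in each over all genes. Without replicate 2 the list-alone counts were 8 cholesterol, 9 excitatory synapse (1 of them higher), 4 axonal, 3 striatal and 2 upper-layer genes, and without replicate 5 there was 1 interneuron gene.

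Among tissues that border the cortex, choroid plexus genes stood at -0.48 ± 0.41 (SD, n = 5) with 9 of 9 negative (adjusted p = 6.29e-05; adjusted p = 0.479 with an estimated correlation). Ttr was at -4.11, -1.89, -4.29, -3.85 and -0.12 on replicates 1 to 5, and Otx2, a transcription factor of choroid plexus epithelium and of the pineal gland, at -1.78 ± 1.26, with its lowest value (-3.41) on replicate 2 and its kaolin signal well above background on 1 of 5 arrays. Erythroid genes stood at -0.31 ± 0.32 with 7 of 9 negative (adjusted p = 0.010; adjusted p = 0.479 with an estimated correlation). That call was lost without replicate 2 (adjusted p = 0.166), with array weights (adjusted p = 0.0568), with median centring (adjusted p = 0.0754) and with the sign of replicate 2 turned (adjusted p = 0.702), over a range that began at 2.3e-05. Adjusted over the list alone, 3 choroid plexus genes and 1 erythroid gene passed, against 0 in each over all genes; without replicate 3 the counts were 0 and 3, without replicate 4 they were 2 and 1, and without replicate 2 they were 3 and 2, with 1 of the 2 erythroid genes higher in kaolin. The choroid plexus genes were Ttr, Otx2 and the potassium channel subunit Kcne2 (-0.54 ± 0.40), and the erythroid gene was Hba-a3. With the choroid plexus, meningeal, ependymal, erythroid and pineal genes left out, an alternative chosen after seeing the data, 17 of the 31 remaining lists were shifted. The lists of these tissues dropped out themselves, and each of the 31 kept its result. Leaving out genes can hardly move the test of lists without them. It therefore cannot tell whether neighbouring tissue adds to the other lists. The meningeal list, at 0.20 ± 0.49 with 15 of 15 positive, missed the threshold (adjusted p = 0.0895) and passed it without replicate 1 (adjusted p = 7.7e-05) and with array weights (adjusted p = 0.0305), over a range up to 0.736.

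The remaining 14 lists were not shifted. Oligodendrocyte and myelin genes stood at 0.02 ± 0.26 (SD, n = 5) with 10 of 17 positive (adjusted p = 0.599), and oligodendrocyte precursor genes at 0.04 ± 0.12 with 6 of 12 positive (adjusted p = 0.847). General astrocyte markers stood at 0.04 ± 0.21 with 7 of 15 positive (adjusted p = 0.861) and endothelial and pericyte markers at 0.03 ± 0.16 (adjusted p = 0.947). In these 4 lists the median over genes, the mean over genes and the list test did not share a sign. Astrocyte markers had a median of -0.01, a mean of 0.05 and an upward test. Precursor genes had a median of -0.0032, a mean of 0.02 and a downward test, and both myelin and endothelial genes positive medians (0.02 and 0.03) and means (0.01 and 0.0056) with a downward test. Lymphocyte and granulocyte markers stood at 0.12 ± 0.19 over 7 members (adjusted p = 0.298). Their median over genes was 0.12, against 0.56 with the processed signals and 0.55 with the authors' values and the software's log ratios, where they did not pass either. Brain extracellular matrix and protease genes stood at 0.14 ± 0.16 (adjusted p = 0.115). With median centring both lists passed (adjusted p = 0.0080 and 0.0231), and without replicate 1 the matrix list passed (adjusted p = 0.0050); their ranges ran up to 0.547 and 0.523 with the preset correlation and to 0.711 and 0.606 with an estimated correlation. Hypoxia-response genes stood at 0.07 ± 0.11 (adjusted p = 0.716), chaperone genes at 0.19 ± 0.24 (adjusted p = 0.244) and neurotrophic factor genes at -0.0033 ± 0.18 (adjusted p = 0.508). Water channel and ion transport genes stood at -0.04 ± 0.15 (adjusted p = 0.244) and passed with the sign of replicate 2 turned (adjusted p = 0.0286, in a range up to 0.734). Respiratory chain genes stood at 0.04 ± 0.16 (adjusted p = 0.716), and median centring turned them to -0.25 with a call downward (adjusted p = 0.0049, in a range up to 0.941). Deep-layer neuron genes stood at -0.04 ± 0.09 (adjusted p = 0.322), hippocampal neuron genes at -0.09 ± 0.07 (adjusted p = 0.115) and thalamic neuron genes at 0.08 ± 0.07 (adjusted p = 0.736). The thalamic list, with 6 of 9 members positive, was the only one to pass fry over all 5 arrays (adjusted p = 0.00059). Its median and mean over genes were both 0.02, and its estimated correlation between genes was -0.11. Fry asks whether a list moves one way and not whether it differs from other genes. The thalamic call in fry was lost without replicate 1 (adjusted p = 0.081) and without replicate 5 (adjusted p = 0.273). Without replicate 2, a set chosen after seeing the data, the axonal, ependymal, upper-layer and striatal lists passed fry too (adjusted p = 0.0378 in each). The thalamic list was at 0.0029 there, and the reactive astrocyte and complement lists did not pass (adjusted p = 0.134 in each). Adjusted over the list alone, 1 member of the myelin list, Neurod1 of the hippocampal list (-0.36 ± 0.20) and the chaperone list's Hsp90aa1 (-0.50 ± 0.24), Hspa8 (-0.33 ± 0.17) and Atf3 (mean 1.39) passed, and 0 members of the meningeal and the other 11 lists did, against 0 in each over all genes. Without replicate 2 these list-alone counts, in either direction, were 2 myelin, 2 hippocampal, 5 chaperone, 5 hypoxia, 5 neurotrophic and 4 water and ion transport genes. Without replicate 1 they were 2 myelin, 0 hippocampal, 1 chaperone, 1 thalamic, 2 matrix and 2 leukocyte genes, without replicate 3 or 4 each was 0, and without replicate 5 there was 1 each of myelin, hippocampal, chaperone, hypoxia and precursor genes. As checks outside the adjustment, housekeeping genes stood at 0.02 ± 0.10 over 12 members, with a positive median over genes (0.04) and mean (0.08) and a downward test (3 passed over the list alone, among them Rpl13a at 0.57 and Gusb at 0.60), and the only sex-linked gene tested, Uty, at -0.04 ± 0.33.

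No single gene passed over all genes, and the genes of smallest unadjusted p in each direction were named by the rule. On the higher side they included Sncg (gamma-synuclein) at 0.99 ± 0.40 (SD, n = 5), Tradd, a death-receptor adaptor, at 0.69 ± 0.30, Gsn (gelsolin, an actin-severing protein) at 0.65 ± 0.25, Azin2 at 0.52 ± 0.16, Echdc1 at 0.39 ± 0.06 and P2rx4, an ATP-gated channel, at 0.37 ± 0.07. On the lower side, 3 were beta-tubulin genes. Tubb2b was at -0.73 ± 0.14 on its brightest probe (rn4 chromosome 17, 37090616 to 37090675) and at -0.20 and -0.25 on its other probes. Tubb5 was at -0.68 ± 0.14 and Tubb4b at -0.64 ± 0.26. The others were Hba-a3, an alpha-globin, at -1.12 ± 0.53, the potassium channel Kcnj14 at -0.57 ± 0.16, the clathrin adaptor subunit Ap2a2 at -0.47 ± 0.16, Ppial4g at -0.47 ± 0.16 and Samd12 at -0.40 ± 0.06. Each of these genes had one sign on 5 of 5 arrays and an adjusted p of 0.243. Picking genes by a small p over the same arrays favours one sign, so this is not separate support. A dye effect of single probes would also give one sign on every array and cannot be told apart from the treatment. The tubulin, Hba-a3 and Ppial4g probes are among the 341 tested probes above a log2 intensity of 15, of which 65.1% had means below 0.

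The genes of the fixed panel reached from C3, at 3.74-fold, down to Ttr, and the probe for Gfap lies on rn4 chromosome 10, 92060835 to 92060894. Il1b was at 0.53 ± 0.53 (SD, n = 5), Tgfb1 at 0.34 ± 0.26 and Aqp4, the astrocyte water channel, at 0.43 ± 0.39. Mbp, a myelin protein gene, was at -0.04 ± 0.35 and changed sign with the scanner software's processed signals and log ratios, with the authors' values, with array weights and without replicate 5. Bdnf was at -0.56 ± 0.59, Vegfa at -0.25 ± 0.22, Gad1 at -0.17 ± 0.28 and Pvalb at -0.13 ± 0.34, the last with the other sign without replicate 5. Aqp1 was at -0.21 ± 0.45, with the other sign when replicate 2 was turned. Slc17a7, the vesicular glutamate transporter, was at 0.08 ± 0.17 and changed sign with median centring. Of the panel, 19 of 20 genes were tested; Tnf was not well above background on any array.

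**Figure D2:**
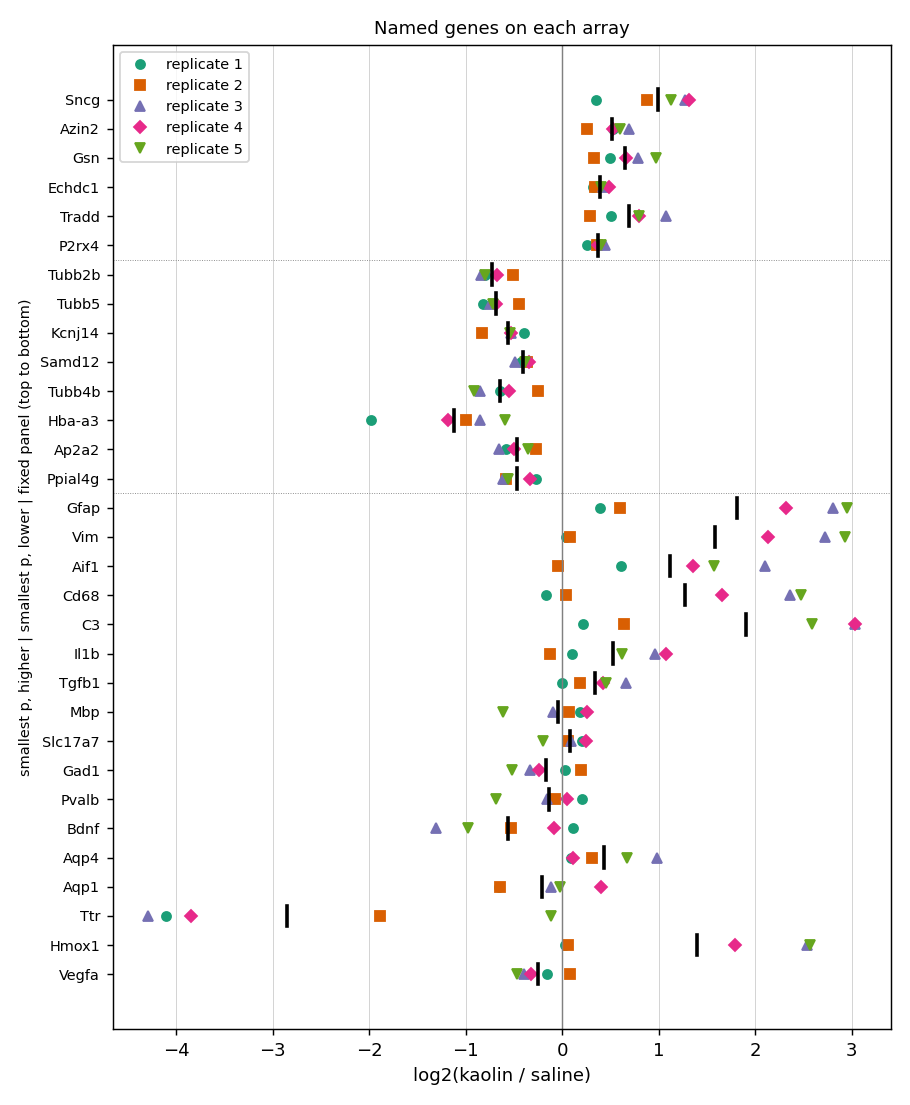
Log2 ratio of kaolin over saline (horizontal axis) of 31 genes taken by the naming rule on each of the 5 arrays (points, coloured by replicate), with the mean over arrays as a black bar. Gfap and C3 have means of 1.81 and 1.90 and Ttr a mean of -2.85, each with an SD over 1.2.

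The test of each probe was limma's intercept, with an adjustment over 29114 probes of 11974 named genes. Against 0 probes past the threshold, 5279 had an unadjusted p under 0.05 (2567 higher and 2712 lower in kaolin), and 3745 probes (12.9%) had one sign on all 5 arrays, where independent arrays would give 6.25%. With the sign of replicate 2 turned, 7107 probes (24.4%) did. Without replicate 2, 1536 probes passed (716 higher, 820 lower, 151 of them by at least 2-fold), and so did 19 of the 35 genes taken by the naming rule, Gfap among them (adjusted p = 0.0479, over a range of settings from 0.0425 to 0.659). Without replicate 1, 1 probe passed, and without replicate 3, 4 or 5, 0 did in limma (2034, 2279 and 3927 at an unadjusted p under 0.05). Other settings gave 22 probes with median centring, 3 with the 10 channels taken as 2 unpaired groups, 3477 with array weights and 489 with the sign of replicate 2 turned, the last chosen after seeing the data. The slide could be examined only in part: slide 1 alone, which is the set without replicate 5, gave 0 probes and 19 lists, slide 2 held 1 array, and slide as a random block gave 0 probes (7578 at an unadjusted p under 0.05) and 20 lists. An exact sign-flip test of 5 arrays cannot reach a two-sided p under 0.0625.

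The arrays differed in how their ratios ran together across genes. Over the 29114 tested probes, the correlation was 0.83 between replicates 3 and 4, 0.57 between 3 and 5, 0.45 between 4 and 5, 0.53 between 1 and 3, 0.48 between 1 and 4 and 0.12 between 1 and 5. Replicate 2 correlated at -0.37 with replicate 1 (-0.33 over all 41012 probes), -0.17 with replicate 3, -0.07 with replicate 4 and -0.06 with replicate 5. These are correlations across genes within a pair of arrays, and genes are not independent replicates. With the sign of replicate 2 turned, the 489 probes past the threshold split into 245 higher and 244 lower, 11 of them by at least 2-fold, and 20 lists were shifted. Probes beyond 2-fold in either direction numbered 274, 90, 1587, 1055 and 715 on replicates 1 to 5.

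**Figure D3:**
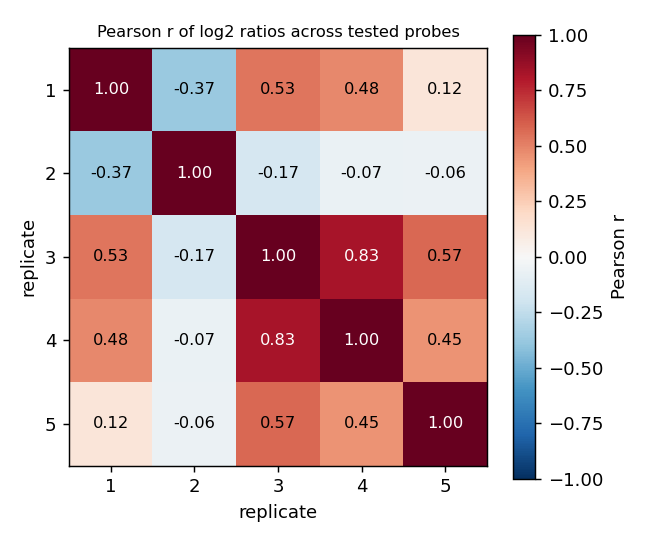
Pearson correlation across the 29114 tested probes between the log2 ratios of each pair of the 5 arrays (rows and columns are replicates, colour and printed value are the correlation). Replicates 3 and 4 have the highest value (0.83) and replicates 1 and 2 the lowest (-0.37).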

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

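Of the tests in this part, those of exchanged samples and of normalization or compression on replicates 1 and 2, the turned sign of replicate 2, and the use of single genes and list medians against reversed dyes, were chosen only after the result was seen.

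Genes of photoreceptors and of melatonin synthesis stood apart on replicate 2. Values on that array lay far below those on the other 4 arrays for Tph1 (-5.90), Gnat2 (-5.41), Prph2 (-3.18), Lrit1 (-2.80), Guca1a (-2.65), Asmt (-2.63), Cngb1 (-2.60), Rom1 (-1.91), Tulp1 (-1.62), Pde6h (-1.61) and Grk1 (-0.92). That is 11 of 16 such genes examined, while chance alone sets an array apart in this way in about 1 of 20 groups; 13 of the 16 had been listed because of their low values on replicate 2, so the count is not a share of genes picked blindly. The kaolin signals of Tph1, Gnat2, Lrit1 and Pde6h were well above background on 1, 3, 2 and 4 of the 5 arrays, so the size of their ratios depends on the background correction. The pineal gland expresses both kinds of gene. Among 92 other single genes, 1 stood apart, also on replicate 2: Car3, a carbonic anhydrase, was at -0.77 there and at 2.42, 2.86, 2.64 and 2.85 on replicates 1, 3, 4 and 5. None of the 35 lists stood apart. Car3 had been picked for its large value without replicate 2, so it was not found blindly either.

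For the photoreceptor and melatonin genes, retinal tissue in the saline sample is argued against, since retina markers that the pineal gland lacks had a median log2 ratio of -0.072 on replicate 2. Pineal tissue in that sample is a candidate explanation that stays open: 13 pineal markers not seen before the test had a median of -0.61, with 5 of them below -1, against medians between -0.12 and -0.0004 on the other arrays. Aanat, which acts in the same pathway as Tph1 and Asmt, was at -0.20 there and between -0.26 and -0.09 elsewhere. As a single gene it does not decide the question. Rcvrn, Neurod4 and Cacna1f were not well above background in any saline sample, so their part in the median carries little weight. The signal lay in the saline channel if the labelled dyes are right. Well above background there were 9 of these 13 markers, against a median of 3.5 in the saline channel of the other arrays. No biological explanation was tested, since the design gives one group of arrays.

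The glial and immune lists lay near 0 on replicates 1 and 2 and not on the other arrays. An exchange of kaolin and saline RNA as the reason for values near 0 is argued against, since it turns a sign and leaves the size, and the lower of the reactive astrocyte medians on these arrays was -0.15. Compressed ratios are argued against by spike-in ranges of 6.08 on both arrays and 6.04 to 6.10 on the others. In the scanner software's own signals, the higher of the 2 reactive astrocyte medians was -0.042. Those signals had also been through a lowess dye normalization, so they cannot exclude a fault that lowess and loess share. A weaker response to kaolin in these samples stays open, and no biological explanation was tested.

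Ratios of replicates 1 and 2 correlated at -0.37 across tested probes. A small number of strongly changed genes is argued against, since the correlation was -0.43 without the 349 probes beyond a log2 of 1 on either array. Reversed dyes on replicate 2 stay open. Of 1536 probes past the threshold without that array, 373 (24.3%) had the same sign on it, which met the bound for reversed dyes set beforehand. Among the 1000 probes of smallest p without an array, 23.6% had the same sign on replicate 2. That share was 55.7%, 95.8%, 97.4% and 60.9% for replicates 1, 3, 4 and 5. Against reversed dyes with a response as large as on replicates 3 to 5, the reactive astrocyte and complement medians on replicate 2 were -0.15 and 0.05. With a weak response such medians stay near 0 in either dye order, as on replicate 1 (0.01 and -0.01). They cannot decide that case. Gfap (0.60) and C3 (0.64) kept the sign of the other arrays on replicate 2. Ttr (-1.89) did too, but as a choroid plexus gene it may follow the tissue taken and not the treatment. Turning the sign of replicate 2 gave 489 probes against 1536 without it. Loss of RNA from 5' ends in 1 sample of a pair stays open too: the median difference between a gene's 3' and 5' probes was -0.090 (SE 0.0061) on replicate 1, 0.04 (SE 0.0046) on replicate 2 and -0.07, -0.07 and -0.02 on the others, past the bound of 0.03 set for no loss and short of the 0.1 set for loss. No biological explanation was tested for this pattern.

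Sign patterns of the 5 arrays were counted in place of splits. There are 16, too few for a share under 0.05. The real pattern gave 0 probes past the threshold in limma and the highest other 489, so 16 of 16 gave as many. For probes changed at least 2-fold the values were 0 and 11, again 16 of 16. With a real count of 0 every pattern must give as many, so these shares decide nothing. At an unadjusted p under 0.05 the real pattern gave 5279 probes and the highest other 8765, with 2 of 16 as large, and the real pattern gave 20 lists and the highest other 22, with 3 of 16 as large. The patterns with 489 and 8765 are the one that turns replicate 2 alone, which points to a structure of the samples.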

How the results depend on the processing

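Turning the sign of replicate 2, leaving out neighbouring-tissue genes and leaving out arrays with an estimated correlation were chosen only after the result was seen. Leaving out saturated spots (there were 0) and scaling average intensity between arrays moved nothing and are not counted here. Over the other alternatives, 1732 single-gene results stayed within 1 SD of their value and short of the threshold (some, such as Mbp, with the other sign). Another 135 newly passed, 73 of them with array weights and 49 without replicate 2. A further 67 moved by more, and 0 lost a call or reversed in limma, where none had passed. Of the list results 696 kept their call with its direction or, where there was none, stayed within 1 SD. The call was lost in 50, of which 20 were with the estimated correlation and 20 with fry, so each of these tests lost every call. Of the rest 7 gained a call, 11 moved and 1 reversed. The 1 reversal was the respiratory chain list under median centring (-0.25 against 0.06); the cause was not tested.

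Against 0 probes changed, median centring gave 22 (0 higher, 22 lower, 9 by at least 2-fold), array weights 3477 (1547 higher, 1930 lower, 470 by at least 2-fold; weights 0.81, 0.46, 1.38, 2.36 and 0.82) and replicate 2 turned 489 (245 higher, 244 lower, 11 by at least 2-fold). Without the pairing of channels on an array, 3 probes passed (0 higher, 3 lower). Leaving out each replicate gave 0 to 1536 probes changed, 0 to 716 higher, 0 to 820 lower and 0 to 151 by at least 2-fold, the highest of each without replicate 2. The other settings gave 0 in limma, with 3421 to 7578 probes at an unadjusted p under 0.05. The causes were not tested.

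Against 20 shifted lists, leaving out each replicate gave 19 to 21, camera with an estimated correlation 0 and fry 1 over all arrays. The other settings gave 17 to 21. The 17 are of the 31 lists that remained when the neighbouring-tissue lists dropped out, so they are not a loss of calls. The estimated correlation gave 0 lists without any single replicate (0 to 3 at an unadjusted p under 0.05). The cause was not tested. Precision is limited by 5 arrays, and signal over background limited the test to 29114 of 41012 probes.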

Other observations

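The results without replicate 2 were chosen for a closer look only after the result over all arrays was seen, as were the genes named here.

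Without replicate 2, 633 of 11973 genes passed in limma, 403 higher and 230 lower in kaolin. The 8 highest of these were the calcium-binding S100a4 at 3.29, S100a6 at 3.02, the carbonic anhydrase Car3 at 2.69 and Lgals3, the galectin of activated microglia and macrophages, at 2.63. The annexin Anxa1 was at 2.45, Plac8 at 2.40, the Fc receptor gene Fcgr2b at 2.38 and Ccl2 at 2.34. The values in this part without replicate 2 are means over 4 arrays, with standard errors from limma between 0.09 and 0.50. On replicate 2 these 8 genes were at -0.64, -0.27, -0.77, -1.07, -0.82, 0.09, -0.01 and -0.19 in the same order. Of the 633 genes, 160 had the same sign on replicate 2. By list, the genes past the threshold included 5 of 19 interferon-response, 4 of 14 antigen-presentation, 3 of 14 reactive astrocyte, 3 of 10 ependymal, 3 of 17 cell cycle, 3 of 18 apoptosis and 2 of 14 microglial genes on the higher side, and 3 of 12 housekeeping genes, which serve as a check. On the lower side they included 3 of 20 cholesterol-synthesis, 3 of 20 excitatory synapse, 3 of 15 axonal, 2 of 9 upper-layer and 2 of 12 striatal genes. Hmgcs1, an early enzyme of cholesterol synthesis, was at -1.06, Elovl6, a fatty acid elongase, at -0.97, the sodium pump subunit Atp1b1 at -0.93 and the secretory granule protein Chgb at -0.91. None of the counts is a result over 5 arrays, where 0 genes passed in limma (2260 at an unadjusted p under 0.05).

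The lowest value without replicate 2 belonged to 1 probe of Sv2b, a synaptic vesicle protein gene, at -3.90 (-3.08, -4.42, -4.57 and -3.54 on replicates 1, 3, 4 and 5, and -0.12 on replicate 2). The other tested Sv2b probe was at 0.0048 ± 0.41 (SD, n = 5) over all arrays, and another, too dim to be tested, at -0.04 ± 0.21. Kcnq3, a potassium channel gene, was at -1.59, and Nrxn3, a synaptic adhesion gene, at -1.14.

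The brightest probes lay low on average. Of 341 tested probes above a log2 intensity of 15, 65.1% had means below 0, with a median of -0.10, and with median centring 94.1% did, with a median of -0.48. The brightest probe of Tubb2b (log2 intensity 16.5) is among them, at -0.73, and its dimmer probes were at -0.20 and -0.25.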
